A study of Sparus aurata with 9 samples.

How the data were processed

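Liver RNA of gilthead sea bream (Sparus aurata) was measured on 9 one-colour Agilent arrays, 3 for each of 3 groups: control fish, fish given a slow-release cortisol implant of 200 µg per g body weight and sampled after 7 days, and fish given the same implant and sampled after 14 days. Per the labels, each array held RNA pooled from 2 fish, so the 9 arrays stand for 18 fish, and the spread between arrays is a spread between pools of different fish. Groups and pool numbers were taken from the sample titles. The labels give the controls no treatment in one place and an implant of coconut oil without cortisol in another, and give no sampling day for them. The protocol also has an untreated group sampled on day 0, and the labels do not say whether the control arrays hold that group. Per the protocol, no fish was fed during the experiment. The design states 36 fish, while the 9 pools make 18.

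Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1, which produced the deposited spot intensity used here: the brightness of the Cy3 dye after background subtraction and detrending within the array, with no scaling between arrays. The authors' value table of the same arrays is on the log2 scale of the background-subtracted intensity for all arrays except cortisol day 7 pool 3. The column of that array is a logarithm to base 20, another deposited scale, which was found by setting each column against the scanner values (largest difference 1.5e-09 on the natural log scale). Its median was 1.24, against medians of 6.44, 6.71 and 6.86 for control pools 1, 2 and 3, 6.38 and 6.87 for day 7 pools 1 and 2, and 7.14, 7.61 and 6.29 for day 14 pools 1, 2 and 3. The table was not centred or scaled between arrays, its empty cells were the spots with a background-subtracted signal of 0 or below, and it was used only as an alternative.

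The main values were log2 of the processed signal minus the 75th percentile of each array over its 43803 non-control spots. Spots marked as outliers were left out and the spots of a probe were averaged, which gave 28793 probes for 15156 sequences. A probe counted as well above background on an array when at least 50% of its spots were marked so, and the 18278 probes well above background on at least 3 of the 9 arrays were tested. The 3 groups were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 6 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the probes tested. A probe was called when its adjusted p was under 0.05. Each cortisol group was compared with the controls, day 14 was compared with day 7, and an F test covered the 3 groups. Where a probe was not well above background on any array of a group, a floored fold was given: the mean of the brighter group against the floored mean of the dimmer group. On each array of the dimmer group the probe's own value was used, or the floor if that was higher. The floor of an array was the lowest log2 value among its probes well above background. It is not a detection limit: the probe CUST_8974_PI419285025 was not well above background on day 14 pool 1 at -1.40, where the floor was -3.44. A floored fold is therefore not a strict lower bound, and the true fold may be smaller.

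The files used here pair no probe with a gene name: none of the 15156 sequence names matched the 32006 genes of the reference table of assembly fSpaAur1.1. The 28 gene lists chosen before the data were examined were therefore not tested, and the rule for named genes, which asked for a gene name and only counted probes known by a contig or clone number, named none. The 4 probes named in the text, 2 that rose and 2 that fell, were chosen after their values were seen, as those with the largest change against control at each time.

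Slide and scan day were read from the file headers and tested as blocks. The comparison was tested on simulated data of 18278 probes, of which 200 were changed. Each probe had its observed mean and a spread that eBayes had shrunk toward a common value, not the observed spread. Probes were drawn independently and without a slide effect. The simulations of unchanged groups in the results used spreads shrunk in the same way. In the simulated comparison of day 7 with control, 6% of the probes changed by 1 log2 unit were called, 68% of those changed by 2, 94% of those changed by 3 and 90% of those changed by 4, with 8 false calls. Other normalizations, filters, blocks, variance models and array weights, and leaving out each array, were tried as alternatives chosen before the data were examined. The planned background correction on mean signals was not run because the files used here hold no such column. It was replaced by normexp of limma on the median signals with an offset of 50, which shrinks differences between dim signals. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.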

Results

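The study used slow-release cortisol implants to keep plasma cortisol high in gilthead sea bream and measured liver transcripts with a microarray. Cortisol is the main glucocorticoid stress hormone of bony fish. The design asked which liver transcripts differed from controls after 7 days of the implant and which differed between 14 and 7 days. Each of the 3 groups had 3 arrays, each with RNA of 2 pooled fish of a stock of 108 g mean weight kept at 15 °C. The probes are known here by probe number and by the sequence they were designed from, so the results are given as counts of probes and sequences, and no gene or pathway is named.

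Between 34.7% and 65.2% of the 43803 non-control spots of an array were well above background. The lowest share belonged to cortisol day 14 pool 1, with 10450 probes well above background, and the highest to cortisol day 14 pool 2, with 19242. Across probes, arrays of the same group correlated at 0.94 on average and arrays of different groups at 0.924, where probes are not independent replicates. The arrays lay on 3 slides scanned on 2 days. Slide 1, scanned on the first day, held control pools 1 and 3 and pool 3 of each cortisol group. Slide 2 held pool 1 of each cortisol group, and slide 3 held pool 2 of all 3 groups. The ratio of spike-in signal to negative controls was 87.0 to 130 on slide 1, 9.77 to 10.97 on slide 2 and 14.2 to 26.8 on slide 3. In the plot of principal components, the first component took 29.2% of the variance, and control pools 1 and 3 lay apart from control pool 2.

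**Figure D1:**
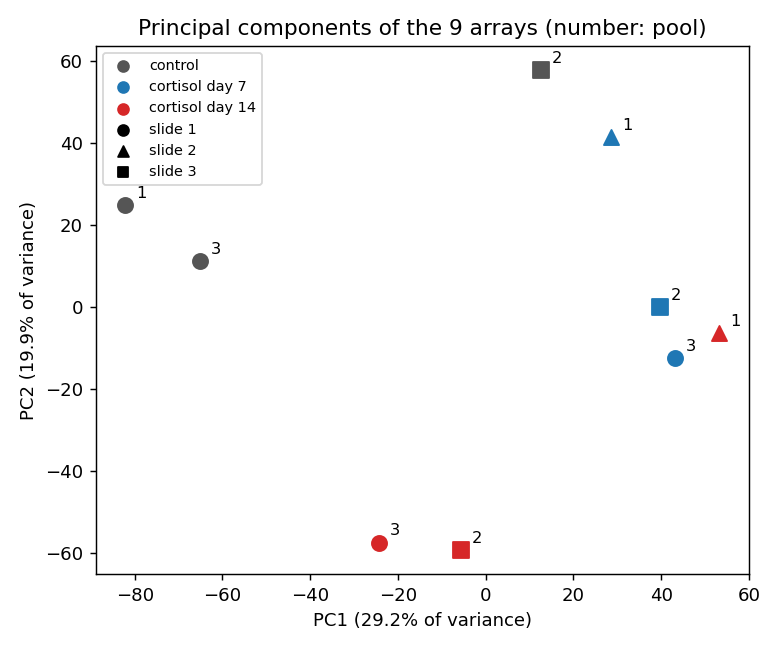
Principal components of the 9 arrays over the tested probes, with the first component (29.2% of the variance) on the x axis and the second (19.9%) on the y axis, in units of log2 signal. Colours give the group, shapes the slide and numbers the pool. Control pools 1 and 3, on slide 1, sit at -82.1 and -65.2 on the first component, and control pool 2, on slide 3, at 12.5. The other arrays of slide 1, day 7 pool 3 and day 14 pool 3, sit at 43.2 and -24.4, so the component does not follow the slide alone.

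After 7 days of the cortisol implant, 52 of 18278 probes differed from control, 24 higher and 28 lower, and they belonged to 44 sequences. Taking the percentile only over probes well above background on all 9 arrays gave 14 higher and 28 lower. For 16 of the 52 the dimmer group was not well above background on any array. With these at their floored fold, the median size of the called changes was 2.16 on the log2 scale (2.26 as fitted), and 36 of the 52 changed at least 4-fold. The probe CUST_2456_PI419285025 rose from 2.90 ± 1.30 in controls to 6.39 ± 0.29 (log2 signal relative to the 75th percentile of the array, SD, n = 3), a change of 3.48 ± 0.55 (SE) with a limma adjusted p of 0.0481. The other 2 probes of its sequence changed by 3.32 and 3.36, with adjusted p of 0.0507 for each. The probe CUST_8974_PI419285025 fell from -0.29 ± 0.37 in controls to -4.89 ± 0.55 (SD, n = 3), with a limma adjusted p of 0.0209. It was not well above background on any day 7 array, and its level there was 18.7-fold lower as a floored fold. The 2 other probes of its sequence changed by -2.63 and -1.18, with adjusted p of 0.0654 and 0.397. Both named calls were lost with slide as a block, with changes of 3.33 (limma adjusted p of 0.0883) and -4.35 (0.0682), the second a fitted size against day 7 arrays at background. Normexp background correction gave changes of 3.28 (0.0651) and -1.57 (0.137). The adjusted p ran from 0.000179 to 0.897 over the 23 alternatives that tested the first probe and from 8.2e-05 to 0.525 over the 22 that tested the second.

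Of 69 pairings of a called probe with another probe of its sequence, 68 had the same direction, and in 16 both were called. Over all 4444 sequences with several measured probes, the first 2 had the same direction in 80.3%. Within slide 1 and within slide 3, all 52 probes had the direction of the whole comparison, but these slides also served to call them. With slide as a block 13 probes were called, of which 8 were among the 52, and with scan day as a block 28. Leaving out control pool 1, control pool 3 or cortisol day 14 pool 3 left 0 calls in limma, with 1774, 1773 and 2438 probes at an unadjusted p under 0.05. Leaving out control pool 2 gave 198 calls, day 7 pools 1, 2 and 3 gave 29, 12 and 30, and day 14 pool 2 gave 11. Quantile normalization gave 18.

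After 14 days, 90 probes of 56 sequences differed from control, 47 higher and 43 lower. Scaling on the median of each array gave 47 higher and 23 lower, and the percentile over probes well above background on all arrays gave 51 higher and 70 lower. For 7 of the 90 the dimmer group was not well above background on any array. With these at their floored fold, the median size of the called changes was 2.16 on the log2 scale, and 57 of the 90 changed at least 4-fold. The probe CUST_16087_PI419285025 was not well above background on any control array and was so on all 3 day 14 arrays. It was 19.1-fold higher as a floored fold, with a limma adjusted p of 0.00931. Its measured values were -0.23 ± 0.15 at day 14 and -5.03 ± 0.73 in controls (SD, n = 3). The other measured probe of its sequence was well above background on 2 of the 3 day 14 arrays and on no control array. That other probe was 15.1-fold higher as a floored fold, with a limma adjusted p of 0.0658, above the threshold. The probe CUST_9365_PI419285025 fell from 1.85 ± 0.75 in controls to -2.998 ± 0.14 at day 14 (SD, n = 3), a change of -4.84 ± 0.78 (SE) with a limma adjusted p of 0.0446, and was well above background on 2 of the 3 day 14 arrays. The other 2 probes of its sequence changed by -4.68 and -4.43, with adjusted p of 0.0816 and 0.0908. With slide as a block CUST_16087_PI419285025 kept its call, with a fitted change of 4.75 against controls at background (limma adjusted p of 0.0274), and CUST_9365_PI419285025 lost it, with -5.32 (0.0565). Normexp gave smaller changes of 2.23 (0.00873) and -2.75 (0.0416). The adjusted p ran from 0.000178 to 0.0736 over the 20 alternatives that tested the first probe and from 0.000413 to 0.999995 over the 22 that tested the second. Array weights gave the lowest values, and the value of 0.999995 came from the authors' table as deposited, with its column to base 20.

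**Figure D2:**
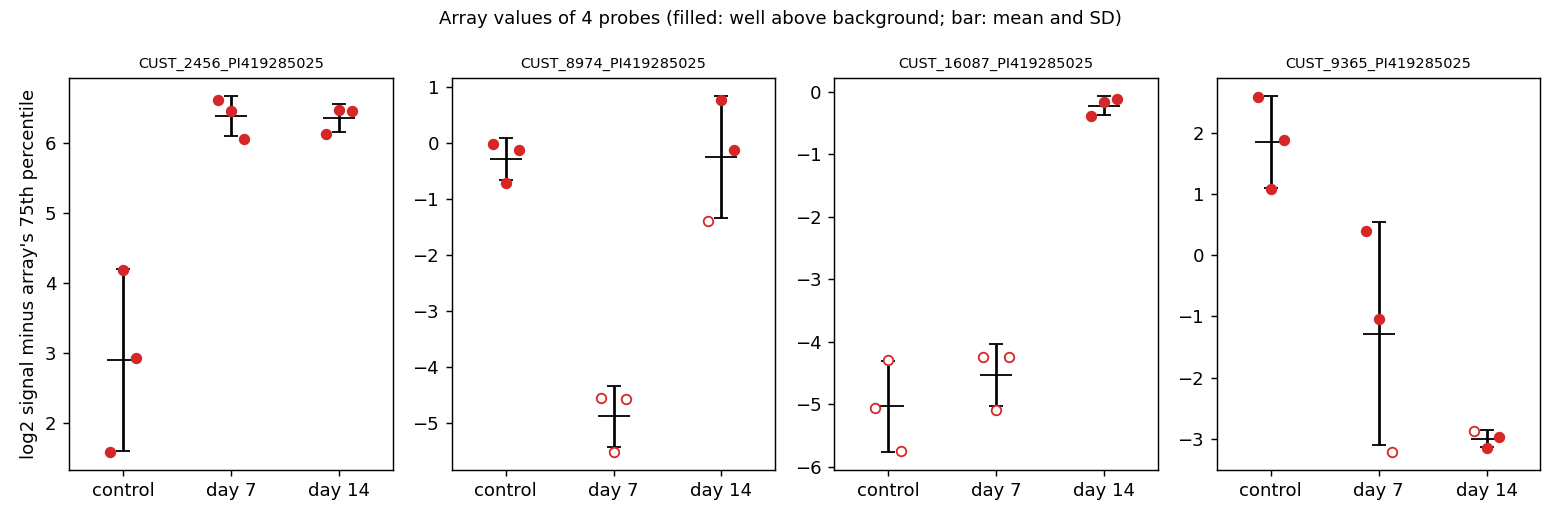
Array values of the 4 named probes, with the group on the x axis and log2 signal minus the 75th percentile of the array on the y axis. Filled circles are arrays on which the probe was well above background, open circles the others, and bars give the mean and SD of 3 arrays; CUST_16087_PI419285025 stood at -0.23 at day 14, against -5.03 in controls.

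Of 147 pairings of a called probe with another probe of its sequence, 146 had the same direction, and in 90 both were called, so that a pair of called probes counts once from each side. Over all sequences with several probes, the first 2 had the same direction in 83.8%. All 90 had that direction within slide 1 and within slide 3, which also served to call them. With slide as a block 77 probes were called, of which 43 were among the 90, and with scan day as a block 50. Leaving out control pool 1, day 14 pool 2 or day 14 pool 3 left 0 calls in limma, with 2250, 2299 and 2585 probes at an unadjusted p under 0.05. Leaving out control pool 3 left 1 call, day 7 pool 2 left 32, and control pool 2 gave 139. Quantile normalization gave 53.

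Between day 14 and day 7, 1 of 18278 probes differed, and 2069 had an unadjusted p under 0.05 in limma, against 914 expected by chance. CUST_16087_PI419285025, not well above background on any day 7 array, was 17.7-fold higher at day 14 as a floored fold, with a limma adjusted p of 0.0287. Its mean at day 7 was -4.53 ± 0.49 (SD, n = 3). As a floored fold, its day 14 level was 17.4-fold higher within slide 1, 14.4-fold within slide 2 and 22-fold within slide 3. With slide or scan day as a block no probe was called, with 2657 and 2425 probes at an unadjusted p under 0.05 in limma, and the fitted log2 difference was 4.30. The call was also lost without control pool 1, day 7 pool 1, 2 or 3, or day 14 pool 2 or 3, with fitted differences of 4.02 to 4.45, all against day 7 arrays at background. Normexp gave 1.82, with a limma adjusted p of 0.410, in a range from 0.000479 to 0.410 over the 20 alternatives that tested the probe. CUST_8974_PI419285025, which fell at day 7, differed from its day 14 level with a limma adjusted p of 0.0892, above the threshold.

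The F test called 73 probes over the 3 groups, and 17 with slide as a block. Of the probes called at each time, 22 were called at both in the same direction, 13 higher and 9 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.0617 higher and 0.0659 lower probes. Of the 52 called at day 7, 51 had the same sign at day 14, and 44 also an unadjusted limma p under 0.05 there. Of the 90 called at day 14, 90 had the same sign at day 7, and 86 such a p. Between the times, 32 of the 52 and 45 of the 90 had an unadjusted limma p under 0.05. A call at a single time therefore does not mean no change at the other, though the shared controls may raise this agreement. At an unadjusted p under 0.05, 1276 probes changed in the same direction at both times, against a mean of 218 and a highest value of 254 in 100 simulations of unchanged groups against shared controls. The fold changes of both times correlated across probes at 0.639, against 0.4996 in the simulations, with a covariance of 0.316 against 0.0986. The 3 controls were too few to be divided, so part of the excess in shared calls may come from the shared controls. The simulations held no slide effect, while slide 1 held 2 of the 3 controls and 1 array of each cortisol group. They, and those with the block given next, also drew each probe independently. In the data, the fold changes of the first 2 probes of a sequence correlated at 0.793 at day 7 and 0.850 at day 14. The simulated values therefore vary too little, and their highest value is no limit for chance. With slide as a block, 10 probes were shared, and 1496 had an unadjusted p under 0.05 at both times in the same direction, against a mean of 262 in simulations fitted with that block. The covariance was then 0.343 against 0.0950. CUST_2456_PI419285025 was among the 22, with a change of 3.46 ± 0.55 (SE) at day 14 and a limma adjusted p of 0.0446, but with slide as a block it was called at neither time (0.0883 at day 7 and 0.0628 at day 14).

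**Figure D3:**
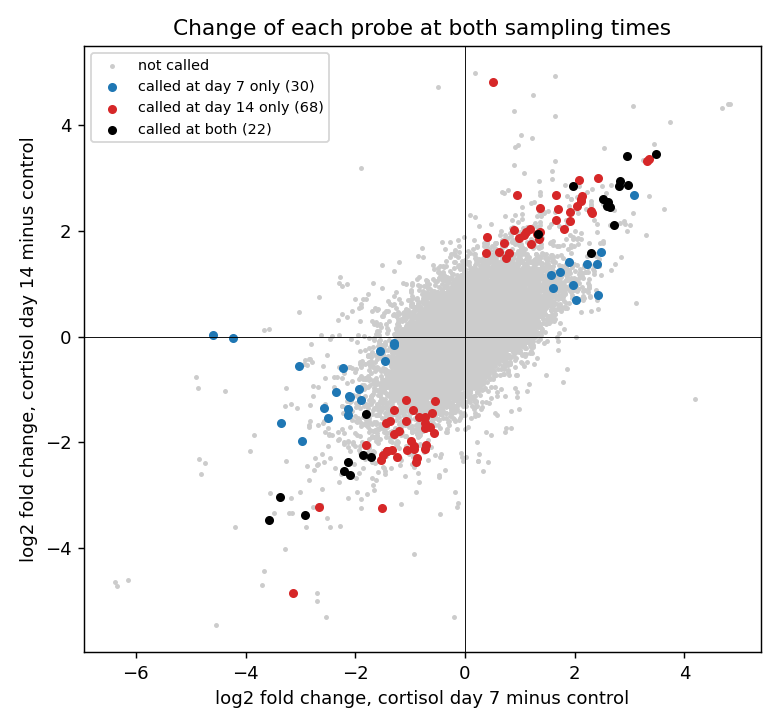
Log2 fold change of each tested probe against control at day 7 (x axis) and at day 14 (y axis). Grey points were not called, and colours mark the 30 probes called at day 7 only, the 68 called at day 14 only and the 22 called at both; the changes correlated at 0.639 across probes.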

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

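The test on the other probe of the sequence, its values within slides, the test of a slide shift by the slide block, all splits with that block and the rankings that ignore the groups were chosen after the results were seen. The splits without a block and the ranking read within slide 3 were chosen before. The probe CUST_16087_PI419285025 is listed because it was called between the sampling times, 17.7-fold higher at day 14 than at day 7 as a floored fold. Its fitted log2 difference was 4.30, against day 7 arrays on none of which it was well above background. The sampling day of the controls is not given, so neither time has a control known to match it. A fault of that probe was weighed, and the other measured probe of its sequence was also higher, by 3.32, with an unadjusted limma p of 0.00443 and an adjusted p of 0.301. Within slide 2 that difference was 0.08, against 4.49 and 5.39 within slides 1 and 3, and this other probe was well above background on 1 of the 3 day 7 arrays, so a fault is not excluded. Of the 10 splits of the 6 arrays, 2 gave as many calls, the highest other split giving 2 against the real 1, and 10 splits are too few for a share under 0.05. A difference in the cortisol response between the times stays open, untested, as do a longer time without food at day 14, a fault and chance.

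The calls against control depended on several arrays. Leaving out control pool 1 or day 14 pool 3, both on slide 1, ended all of them. Leaving out control pool 3, also on slide 1, left 0 and 1, and leaving out day 14 pool 2, on slide 3, left 11 at day 7 and 0 at day 14. Without day 7 pool 3, the remaining array of slide 1, there were 30 at day 7 and 120 at day 14. A difference between slide 1 and the others was weighed by ranking sequences on the arrays off slide 3 and reading their direction within slide 3. The direction was the same for 66% of 200 sequences at day 7 and for 83.5% at day 14, against 56.8% and 57.2% of all sequences. These shares lay above the bound set in advance, but that bound took sequences as independent and was wrong. Rankings of the same arrays that ignored the groups, each read in both directions, gave as high a share in 10 of 36 cases at day 7 and in 4 of 36 at day 14. They were read in pairs of a treated and a control array, of which most lay on different slides, and only 2 of 18 rankings at each time were read within slide 3. In their higher direction these gave 50% and 61% at day 7 and 68% and 77.5% at day 14. All were below the observed shares, but 2 rankings are too few to decide. A shift common to all arrays of a slide was weighed by fitting slide as a block. The median size of the called changes was 2.29 with the block and 2.26 without at day 7, with a median SE of 0.295 and 0.300, and 2.16 with and without it at day 14, with 0.290 and 0.308. These probes were chosen by the fit without the block. Each of the 52 probes kept 0.878 to 1.10 of its change and each of the 90 kept 0.896 to 1.14. That was largely fixed by the choice, because a shift common to a slide widens the spread within groups that span slides, which makes a call less likely. By the design, slides 1 and 3 held control and cortisol arrays, and a shift alone would leave these alike within a slide. The compared groups did not overlap in any of the 52 or 90 probes. That too was nearly fixed by choosing probes with a low p, so it does not decide on such a shift. The block removes a shift common to all arrays of a slide, so such a shift is not the source of calls made with the block. The calls themselves were not all kept: 13 probes were called at day 7, 8 of them among the 52, and 77 at day 14, 43 of them among the 90, where the residual degrees of freedom fell from 6 to 4. With the block the other splits of the 6 arrays gave 0 at day 14. At day 7, however, the split with control pools 1 and 3 and day 7 pool 1 gave 946. Only slide 1 held both sides of this split, and there it set control pools 1 and 3 against day 7 pool 3. That is part of the real comparison. The fit also kept the day 14 arrays, which linked the sides across slides 2 and 3. There day 7 pool 1 was set against control pool 2 and day 7 pool 2, which is not the real comparison. The 946 calls therefore do not rest on the real comparison alone, and they cannot tell a structure of the arrays from the group difference. A slide effect that differs between arrays or probe levels is removed by no block and cannot be told apart from the treatment, because each slide holds too few arrays. The biological difference between the groups stays open.

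For day 7 the real comparison gave 52 calls and the highest of the other splits 1, and for day 14 it gave 90 against 0, with 1 of 10 splits as large in each case, too few for a share under 0.05. For the F test, 2 of 100 drawn splits gave as many calls as the real 73, which excludes chance at 0.05 only if arrays can be exchanged across slides. The other such split gave 173 and put control pools 1 and 3 with day 14 pool 3, all on slide 1, in a group. The splits of 3 against 3 that put control pools 1 and 3 with the slide 1 array of day 7 or of day 14 gave 0 calls. The F test with slide as a block called 17, and with the pool number as a block 0. Of the 72 splits that keep the arrays of each group on each slide, 2 gave as many as 17 with the slide block, a share under 0.05. That argues against chance alone within slides, but less firmly than a planned test, as these splits were chosen after the results were seen. The split other than the real one gave 40 and kept the 3 controls together, exchanging pool 1 of the cortisol groups.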

How the results depend on the processing

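Normexp on median signals, the authors' table as deposited, sequence means and the slide block for shared calls were chosen after seeing the data. No count of calls held within 1.5 times under all alternatives, and where no construction is named the cause was not tested. At day 7, day 14, day 14 against day 7 and in the F test, in this order, the counts were 52, 90, 1 and 73. With no filter on dim probes they were all 0, with more probes tested. With only probes above background on all 9 arrays they were 117, 326, 0 and 166, with fewer tested. With trend and robust variances they were 109, 189, 1 and 134. Array weights gave 7964, 3856, 2671 and 8624, with weights of 5.28 on control pool 3 and 5.41 on day 7 pool 2 against 0.297 on control pool 2. Quantile normalization gave 18, 53, 1 and 18, and the authors' table on the log2 scale 23, 51, 0 and 29. With only the groups compared, with fewer arrays, the first 3 were 0, 46 and 1. Slide as a block gave 13, 77, 0 and 17, and scan day 28, 50, 0 and 31. Normexp gave 11, 62, 0 and 20, and sequence means 44, 42, 0 and 39. The table as deposited gave 0 in every test, where the base 20 column also turned the day 7 change of CUST_2456_PI419285025 to -0.29. Shared calls were 22, and 11 with quantile normalization, 9 with normexp and 10 with the slide block. Leaving out an array in turn gave 0 to 198 calls at day 7, 0 to 139 at day 14, 0 to 5 between the times, 0 to 109 in the F test and 0 to 62 shared. In limma fits with 0 calls, other than the table as deposited, 1773 to 2886 probes had an unadjusted p under 0.05 at day 7, 2250 to 3010 at day 14 and 923 to 2657 between the times. Scaling on the array median moved the median log2 difference of day 14 against day 7 by 0.109. The pool number as a replicate block gave 0, 44, 0 and 0. Same-numbered arrays were not paired by the rule used: 5 of their 9 correlations of deviations were over 0.1, from -0.263 to 0.378, and 6 of 9 arrays correlated best with their own number. Apart from control pool 1, the pool number follows the slide, so neither these correlations nor the pool number block can tell pairing from a shared slide. The planned normexp on mean signals, its shared calls and the gene list tests were not run. Signal over background limits the probes near the floor, most on day 14 pool 1.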

Other observations

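The contrast of both times, its splits within slides, the name families and the test of the log base were chosen after the data were seen. The prediction on the splits of that contrast without a block was written before their result. Taking the 6 cortisol arrays together against the 3 controls called 123 probes, 67 higher and 56 lower. Of the 84 splits into 6 and 3 arrays, 2 gave as many calls, which excludes chance at 0.05 only if arrays can be exchanged across slides. The other was the split with control pools 1 and 3 and day 14 pool 3, all on slide 1, which gave 345 and points to a structure of the arrays other than the groups. The split with control pools 1 and 3 and day 7 pool 3, also all on slide 1, gave 8. With slide as a block the same fit called 33. Of the 18 splits that keep the number of controls on each slide, 1 gave as many with the block, the highest other giving 0, and 18 splits are too few for a share under 0.05. With the 3 groups fitted separately, this contrast called 65 probes with slide as a block and 96 with scan day.

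A switch of transcripts on or off with cortisol was tested as a hypothesis, and chance was not excluded. No probe was well above background on all 6 cortisol arrays and on no control array, and 14 probes showed the reverse. Day 14 pool 1 had 10450 probes well above background, against 15427, 15223 and 18540 on control pools 1, 2 and 3. That works against the first pattern and for the reverse, so these counts cannot decide on a switch. Of the 84 splits, 25 gave at least as many, and the highest of the other splits gave 399, with control pool 3 and day 14 pools 2 and 3, the arrays with the most spots well above background.

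None of the 100 brightest probes was called in any comparison. With 52, 90 and 1 calls among all 18278 probes, few or none would be looked for among 100, so this does not set bright probes apart. At an unadjusted limma p under 0.05 there were 3 of the 100 at day 7, 10 at day 14 and 8 between the times. Over all 18278 probes there were 2800, 3225 and 2069. Of 17 families of sequence names, cDN05 had a median of -0.27 between day 14 and day 7, with an adjusted camera p of 0.0188 in the limma package and an adjusted p of 0.103 with an estimated correlation, and cDN13 a median of -0.20, with 0.0343 and an adjusted p of 0.596.

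In the authors' value table, the column of day 7 pool 3 had a median of 1.24, far below the others. A logarithm to base 20 was tested as the reason, and after conversion to the natural log the column matched the background-subtracted signal of that array with a largest difference of 1.5e-09 over the spots. No biological explanation was tested for this column.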
